A study of Equus caballus with 78 samples.

How the data were processed

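Small RNA libraries of extracellular vesicles, the membrane-bound particles that cells release into body fluids, were analysed from horses in a model of osteoarthritis, the degenerative joint disease. The labels give 78 libraries from 4 horses: 26 of plasma, 26 of synovial fluid (the lubricating fluid of a joint) from a joint named OA and 26 from a joint named CTRL. They give 7 time points (0, 10, 35, 42, 49, 56 and 63) without a unit, and they do not say how the disease was induced. Fluid, joint and time point make 21 groups of 3 or 4 horses. No library of horse 4 at time point 10 or of horse 2 at time point 63 was analysed here.

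Per the labels' protocols the libraries were made with the TriLink CleanTag kit. Per the submitters' processing notes cutadapt, Bowtie and edgeR were used with the horse genome build EquCab3.0, while their versions, their settings and how reads shared by near-identical microRNAs were counted are not given in the sources used here. The deposited files hold whole-number read counts for 690 horse microRNA names and for synthetic spike-in sequences named UniSp. They also hold 2 deposited normalized columns, RPM of a library total and reads relative to the microRNA sum. The counts were the basis of every test. The RPM column served only to recover each library total, and the divisor of the other column equalled the sum of the microRNA counts with a largest difference of 0 reads. Spike-in reads stayed out of library sizes. UniSp2, read as a spike-in from its name, was the most frequent listed sequence in 77 of 78 libraries, with a median of 36.1% of the library total. The files used here list no RNA class other than microRNA and spike-ins, so the shares of RNA classes planned before the data were examined were replaced by microRNA reads as a percent of the library total.

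Library totals ran from 2029244 to 12613572 reads, but microRNA reads only from 3916 to 1865513, with medians of 14055 in plasma, 26141 in CTRL-joint fluid and 42865.5 in OA-joint fluid. The 10 shallowest libraries, 9 of them plasma, held 3916 to 8902 microRNA reads. Levels are given as CPM of the microRNA reads, with TMM scaling in the tests and without it in the figures and in the means of libraries. Of the 690 names, 270 had a read in some library. Over 139 features and 52 synovial fluid libraries, 3469 values were 0, where Poisson counting at the mean level of each feature would leave 81.2, and 74 features were at 0 in over 26 of the 52. That mean level is taken over all 52 libraries, so differences between horses, joints and time points can add to the values at 0. Intervals and floors therefore cover counting error only, and not the spread between libraries, whatever its source. A group at 0 reads was set at a floor of 3 reads over the group, and the bound given is the lower of those with TMM-scaled and with unscaled library sizes. Where a group held 1 to 3 reads, a ratio of the reads pooled over the group is given with its exact 95% binomial interval. That interval does not measure the spread between horses. Counts of miR-199a-3p and miR-199b-3p differed by a median of 0% (at most 11.3% in a library) and those of miR-103 and miR-107a by a median of 0% (at most 92.9%), so the members of a pair are not read as independent microRNAs.

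Features were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling, filterByExpr with a count minimum of 10) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The horse was the replicate in the sums per horse and within each group. Plasma against CTRL-joint fluid, and OA joint against CTRL joint after time point 0, used counts summed per horse, 4 sums against 4. Comparisons of joints at a time point and tests over time in a joint used all 52 synovial fluid libraries in 1 fit of 14 groups. Plasma over time used 26 libraries in 7 groups. Tests over time were F-tests of 6 contrasts against time point 0, followed by the single contrasts. The change over time was compared between joints with the 6 interaction contrasts. 16 lists of microRNAs (by cell type: erythrocyte, platelet, endothelial, myeloid leukocyte, lymphocyte, fibroblast and mesenchymal, chondrocyte, liver, skeletal muscle, epithelial; by response: inflammation-induced; by family or cluster: let-7, miR-17~92 with its relatives, miR-29, miR-30, DLK1-DIO3) were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated one, and with fry, where a list had at least 3 tested members. Lists overlap: miR-126 stands in the platelet and endothelial lists, and miR-25 and miR-92a in the erythrocyte and miR-17~92 lists. Single values were compared by two-sided exact permutation tests, enumerating every arrangement in Python 3.11.15 with numpy 2.4.6; scipy 1.17.1 adjusted the 3 spike-in comparisons. The features, lists, tests and most alternatives were set before the data were examined. The named features were, per comparison, the 12 higher and 12 lower with the smallest adjusted p, or the 3 smallest unadjusted p in each direction where none passed, with list members and the 10 most abundant of each fluid. Beyond that rule, miR-143, let-7a and let-7e among the calls of plasma against CTRL joint, and which list members the text names, were chosen after their values were seen.

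The replicate number of the labels is the horse, so equal numbers mark the same animal and pair the samples. Deviations from the group means, averaged over the time points of a horse, were nevertheless hardly correlated between plasma, CTRL joint and OA joint of the same horse. Over 64 features, 1 of 12 correlations exceeded 0.1, and they ran from -0.099 to 0.233. Libraries of the same horse and fluid at different time points were not compared in this way. Fits of single libraries without a block take them as independent. The fits were made without a block, as set beforehand, and the blocked value is given where it changes a call. Within groups, all 108 pairs of libraries differed beyond sampling noise (lowest chi-square per degree of freedom 45.6), so no library was counted as a repeat. The sequencing lane, read from the names of the deposited files, was 1 for all 26 plasma libraries, for 8 CTRL-joint and for 2 OA-joint libraries, and otherwise 2. Alternatives were RLE scaling, library size alone, no filter, a count minimum of 50, DESeq2 1.42.0, horse as a block and lane as a covariate. Others were fits of the compared groups only, mean log2 CPM per horse (prior count 2) in limma, and each horse left out. DESeq2 was run with its poscounts size factors, without its independent filtering and without its cutoff for outlying counts. A feature with outlying reads in a single library was thus not held back there. RLE moved the median log2 fold of the 126 features of plasma against CTRL joint by 0.14 against TMM.

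The fits were tested on simulated counts, with 30 changed features in each of 10 simulations. Counts were drawn from the mean share of each feature over all samples of the fit, the real depths and the dispersion trend. They held no effect of horse and no dispersion of single features, so the rates below hold for that simpler setting. For plasma against CTRL joint the test called 53% of features changed 16-fold, 13% at 4-fold and 5% at 2-fold, and 0.313% of unchanged features. For the joints after time point 0 these were 59%, 26%, 2% and 0.115%. For the joints at time point 35 the test called 4% of features changed 16-fold and 0% of the others, although 11.4% of unchanged features had an unadjusted p under 0.05. Tests over time were too liberal in these sparse simulated counts. Among unchanged features of the simulated OA joint over time, 21.7% had an unadjusted p under 0.05 and 3.49% were called, and in the CTRL joint 20.6% and 3.03%. For the difference between joints these were 21.0% and 1.93%, and for plasma over time 10.0% and 0.484%. At 16-fold, 35%, 43%, 10% and 16% were called in these 4 tests.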

Results

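Extracellular vesicles carry microRNAs, short RNAs that repress matching messenger RNAs, and the series followed them in plasma and synovial fluid of 4 horses over 7 time points to compare a joint with osteoarthritis (OA) with a control joint (CTRL). MicroRNA made up a small part of each library, with a median of 0.287% of the library total in plasma, 0.484% in CTRL-joint fluid and 0.5677% in OA-joint fluid (n = 26 libraries each). Reads of 17 microRNAs were present in every plasma library, of 26 in every CTRL-joint library and of 22 in every OA-joint library. The 10 most frequent microRNAs took a median of 75.8%, 61.7% and 64.4% of the microRNA reads, respectively. In 3 plasma libraries, 1 each of horses 2, 6 and 8, microRNA was over 5% of the library total, up to 18.6%, and these 3 held 84.1% of all plasma microRNA reads.

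**Figure D1:**
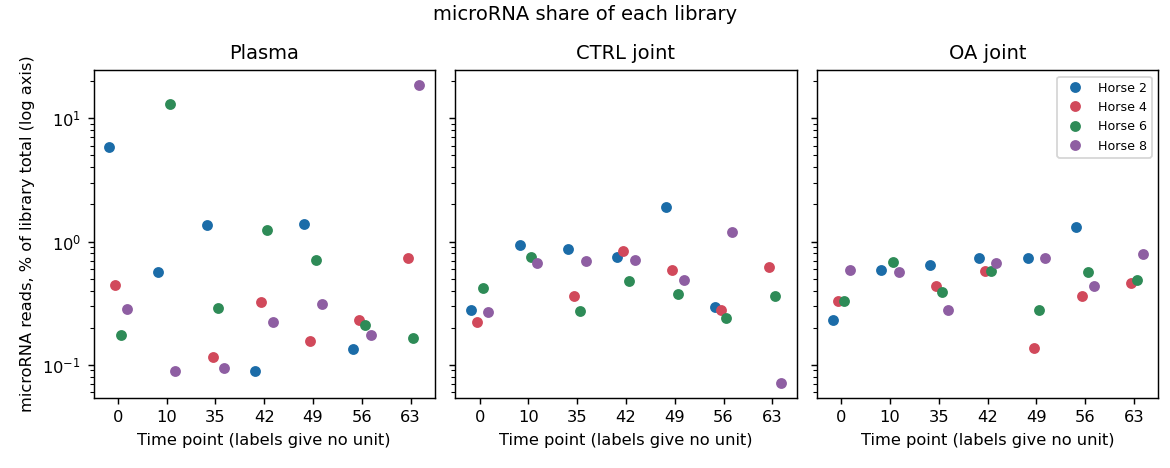
MicroRNA reads as a percent of the library total (log axis) by time point, 1 point per library, coloured by horse, for plasma, CTRL joint and OA joint. The plasma libraries of horse 2 at time point 0 (5.86%) and horse 8 at time point 63 (18.6%) and 1 library of horse 6 lie above all 52 synovial fluid libraries, which end at 1.91%.

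By the mean of library CPM, plasma vesicles were led by miR-486-5p, a microRNA abundant in red blood cells, at 370538 ± 60877 CPM (SD, n = 4 horses). It was followed by miR-21, a widely expressed microRNA induced in inflammation and fibrosis, at 97132 ± 18467 CPM, and by miR-92a at 38121 ± 19119 CPM. In synovial fluid the 10 most frequent microRNAs took a smaller median share of the reads, as given above. More microRNAs had a read in at least 1 library in plasma (234) than in the CTRL joint (188) or the OA joint (194). In the CTRL joint miR-26a (97337 ± 17586 CPM), let-7c (93526 ± 2612 CPM) and miR-10b, encoded within a HOX gene cluster, at 83204 ± 13491 CPM led, and miR-486-5p stood at 64172 ± 15835 CPM. The OA joint had the same leading microRNAs, with let-7c at 113388 ± 7056 CPM, miR-26a at 105507 ± 5319 CPM and miR-10b at 83357 ± 8494 CPM. The mesenchymal microRNA miR-199a-3p, whose counts hardly differ from those of miR-199b-3p, stood at 45131 ± 5075 CPM in the CTRL joint and 58224 ± 17659 CPM in the OA joint. These means weight each library equally, whereas the tests below use counts summed per horse, in which deep libraries weigh more. In those sums the plasma order turns: miR-21 (191157 ± 58775 CPM) stood above miR-486-5p (133042 ± 112789 CPM), and miR-221 (87489.8 ± 33663 CPM) above miR-92a (21520.2 ± 16607 CPM).

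The comparison of fluids asked how vesicle microRNAs of plasma differ from those of the CTRL joint. miR-126-3p, abundant in endothelial cells and platelets, was higher in plasma by a log2 fold of 2.33 (SE 0.40, adjusted p = 0.0015), at 38205 ± 15376 against 7604 ± 2267 CPM in the horse sums (n = 4 each). miR-221, a seed relative of miR-222, was higher by 2.05 (SE 0.43, adjusted p = 0.00555) and miR-21 by 1.69 (SE 0.39, adjusted p = 0.00872). Synovial fluid held more miR-10b (log2 fold -4.02, SE 0.57, adjusted p = 0.000927), at 76047 ± 25001 against 4702 ± 3373 CPM. It also held more let-7c (-2.91, SE 0.78, adjusted p = 0.0158), miR-199a-3p (-2.23, SE 0.35, adjusted p = 0.000927) and miR-26a (-1.68, SE 0.35, adjusted p = 0.00555). Each of these differences had its direction in 4 of 4 horses.

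In total 27 of 126 features passed in edgeR, 13 higher and 14 lower in plasma, with the near-identical miR-199a-3p and miR-199b-3p counted as 2. Among the others higher in plasma were miR-125b-5p (2.55), miR-127 (2.20), miR-31 (2.04), miR-100 (1.98), miR-126-5p (1.90), miR-27a (1.90), miR-29a (1.88), miR-222 (1.78), miR-143 (1.44) and miR-99a (1.41). Lower were miR-28-3p, miR-199b-3p, miR-146b-5p (-2.50), miR-30d (-2.43), miR-148a (-2.22), miR-423-5p (-2.07), let-7e (-2.05), miR-25 (-1.90), let-7a (-1.82) and miR-16 (-1.80). In TMM-scaled CPM of the horse sums, miR-27a was higher in 3 of 4 horses, and the other 26 had their direction in 4 of 4. Without the 3 plasma libraries rich in microRNA 2 of 106 features passed, of which 1 was among the 27, and 25 had an unadjusted p under 0.05. The folds of the 27 had the same direction there, most of them smaller, such as miR-126-3p (1.57, SE 0.56), miR-21 (1.27, SE 0.31), miR-26a (-1.08, SE 0.38) and miR-199a-3p (-1.76, SE 0.55). Single horses did not all keep that direction (CPM without TMM scaling). In horse 8, where 96.2% of the plasma microRNA reads came from its rich library, miR-126-3p then stood at 2249 CPM against 7854 CPM in the CTRL joint. Also lower in plasma there were miR-221 (16020 against 19211 CPM) and miR-99a (1070 against 10885 CPM), while miR-21 stayed higher (62394 against 45143 CPM). Without horse 6 there were 9 calls and without horse 8 there were 8. The 2 called without the 3 libraries were miR-10b (-2.73, SE 0.51, adjusted p = 0.0103; range over all settings 7.64e-22 to 0.253) and miR-486-5p, which then was higher in plasma by 3.34 (SE 0.52, adjusted p = 0.00438; range 9.49e-18 to 0.561). With all libraries miR-486-5p was not called (1.21, SE 0.60, adjusted p = 0.212). With horse as a block miR-27a, let-7e and miR-143 no longer passed (adjusted p = 0.0693, 0.0648 and 0.0515), while miR-451, miR-150, miR-215 and miR-122 did (0.0187, 0.0187, 0.0274 and 0.0492, all lower in plasma).

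Lane moved with fluid: all 26 plasma libraries were in lane 1 and 18 of 26 CTRL-joint libraries in lane 2. In lane 1 alone, with CTRL-joint libraries of 3 horses, 1 of 123 features passed (miR-10b, -3.93, adjusted p = 0.0174) and 36 had an unadjusted p under 0.05. miR-126-3p stood there at 2.49 and miR-199a-3p at -2.33, while the direction of miR-16 (0.90) and miR-25 (0.50) turned. The direction of miR-99a (-0.23) turned in limma on mean log2 CPM per horse, and that of miR-125b-5p (-0.053), miR-423-5p (0.74) and let-7a (0.088) at time point 0 alone.

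**Figure D2:**
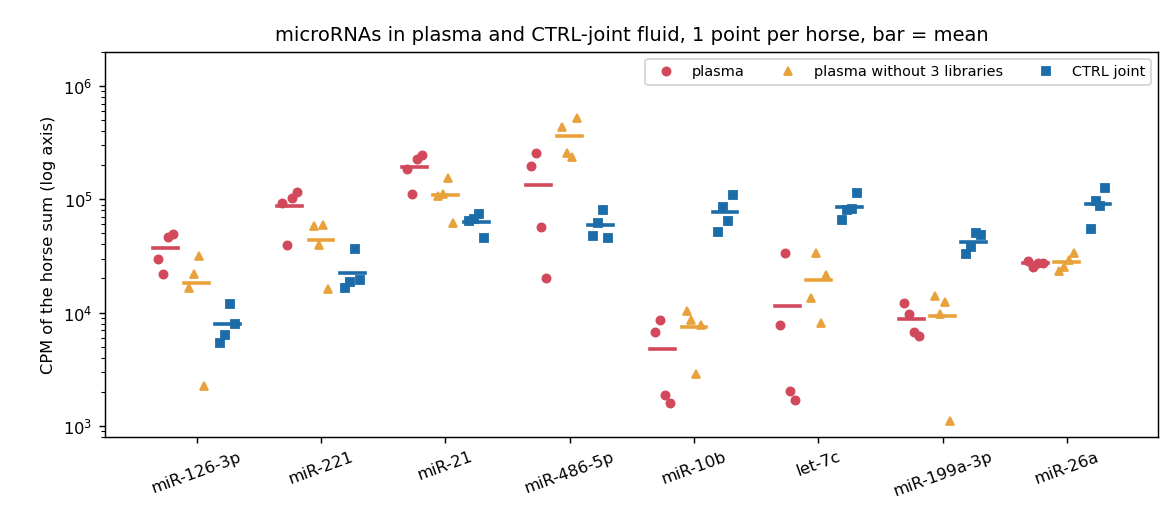
CPM of the counts summed per horse (log axis, no TMM scaling) for 8 microRNAs, 1 point per horse and a bar for the mean, in plasma, in plasma without the 3 libraries rich in microRNA, and in the CTRL joint. Without those libraries the plasma mean of miR-486-5p goes from 133042 to 363940 CPM, and miR-10b lies at 7417 against 77815 CPM in the CTRL joint.

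By cell type, 4 of 7 platelet-list microRNAs were higher in plasma and none lower, namely miR-126-3p, miR-221, miR-126-5p and miR-222, and 4 passed when adjusted over the list alone. The platelet list took 22.9% to 25.9% of the microRNA reads in the 3 libraries rich in microRNA, against a median of 5.67% in the other 23 plasma libraries, of which 1 reached 22.9%. Of 3 endothelial microRNAs, both arms of miR-126 were higher (2 adjusted over the list alone), at 5.53% to 7.40% of reads in the 3 libraries and a median of 1.85% in the others (highest 8.81%). Of 14 fibroblast and mesenchymal microRNAs, 4 were higher (miR-125b-5p, miR-100, miR-99a, miR-143) and 3 lower (miR-10b and the near-identical miR-199a-3p and miR-199b-3p), with 7 adjusted over the list alone. Their list took 13.3% to 14.9% of reads in the 3 libraries against a median of 6.05% (highest 16.5%). Of 6 erythrocyte microRNAs, miR-16 and miR-25 were lower, and 3 adjusted over the list alone. That list took 2.27% to 6.43% of reads in the 3 libraries against a median of 51.9% in the others. Of 7 let-7 microRNAs, let-7a, let-7c and let-7e were lower (3 adjusted over the list alone, 1 of 7 with RLE scaling), at 1.46% to 1.91% of reads in the 3 libraries against a median of 3.36% (highest 10.7%). Without the 3 libraries miR-10b of the mesenchymal list and miR-486-5p of the erythrocyte list were the members that passed.

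In the inflammation-induced list miR-21 was higher and miR-146b-5p lower among 5 (2 adjusted over the list alone), while miR-146a stood at -1.22 (SE 0.63, adjusted p = 0.227). In the chondrocyte list miR-27a was higher and miR-148a lower among 5 (2 adjusted over the list alone), and the cartilage microRNA miR-140-3p stood at -2.29 (SE 1.86, adjusted p = 0.484). 1 microRNA was lower in each of the lymphocyte (7 tested, miR-28-3p; 2 adjusted over the list alone), myeloid leukocyte (6, miR-146b-5p; 1), miR-17~92 (7, miR-25; 1) and miR-30 (3, miR-30d; 1) lists. In the miR-29 list miR-29a was higher among 2 (1 adjusted over the list alone). None passed among 3 liver, 3 epithelial and 2 skeletal muscle microRNAs, the liver microRNA miR-122 at -3.28 (SE 2.05, adjusted p = 0.302). As a set, the DLK1-DIO3 list, an imprinted cluster, stood higher in plasma with camera (adjusted p = 0.0117), though miR-127 was its single called member among 9 (1 adjusted over the list alone). Its camera adjusted p = 0.487 with an estimated correlation, and no list passed camera without the 3 libraries. In those libraries the DLK1-DIO3 list took 1.77% to 2.77% of reads against a median of 0.418% (highest 4.15%) in the others. The other 13 tested lists did not pass camera. By fry, which asks whether members differ at all rather than more than other features, 7 lists passed: higher in plasma DLK1-DIO3 and platelet (adjusted p = 0.0257 each) and endothelial (0.0395), lower let-7 and miR-30 (0.00607 each), myeloid leukocyte (0.0427) and lymphocyte (0.0437). Fry was not run without the 3 libraries, so how far these 7 calls rest on them is not known.

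The comparison of joints asked whether OA-joint vesicles differ from those of the CTRL joint of the same horses. Over the time points after 0 no feature passed: 0 of 117 in edgeR, with 10 at an unadjusted p under 0.05, and 4 in DESeq2, all lower in the OA joint. The smallest p belonged to miR-215, a relative of miR-192, at 1170 ± 409 CPM in the OA joint against 7437 ± 7237 CPM in the CTRL joint (log2 fold -2.67, SE 0.64, adjusted p = 0.113, n = 4 each). The red blood cell microRNA miR-451 stood at -1.42 (SE 0.38, adjusted p = 0.123), miR-25 at -1.35 (SE 0.39, adjusted p = 0.123) and its seed relative miR-92a at -1.22 (SE 0.36, adjusted p = 0.123). All 4 were lower in the OA joint of 4 of 4 horses, though miR-215 of horse 8 by little (1738 against 1818 CPM without TMM scaling). miR-486-5p instead stood at 0.02 (SE 0.26, adjusted p = 0.985). On the other side were let-7a (0.71, SE 0.29, adjusted p = 0.418), higher in 4 of 4 horses, miR-30c (3.48, SE 1.86, adjusted p = 0.682) and miR-1180, with 184 reads against 1 (ratio 198, 95% interval 35.1 to 7865; adjusted p = 0.418).

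With horse as a block, 3 features passed, all lower in the OA joint: miR-215 (-2.14, SE 0.65), miR-451 (-1.28, SE 0.36) and miR-25 (-1.24, SE 0.37), each at an adjusted p = 0.0411. In limma on mean log2 CPM per horse the direction of miR-25 turned (0.29, adjusted p = 0.761). Over all settings the adjusted p ran from 0.000622 to 0.968 for miR-215, from 0.000817 to 0.968 for miR-451 and from 0.00209 to 0.761 for miR-25. In the CTRL joint of horse 2 at time point 49 miR-92a took 15.3% of the microRNA reads, miR-451 8.90%, miR-25 7.75% and miR-215 2.63% (median of miR-215 in the other CTRL libraries 0.00295%). Without that pair of libraries the blocked fit called 2, miR-451 (adjusted p = 0.00854) and miR-25 (0.0293), and the unblocked fit 0 of 111 features in edgeR. In that unblocked fit miR-215 stood at -1.83 (SE 0.57, edgeR adjusted p = 0.31), miR-451 at -0.88, miR-25 at -0.80 and miR-92a at -0.68.

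**Figure D3:**
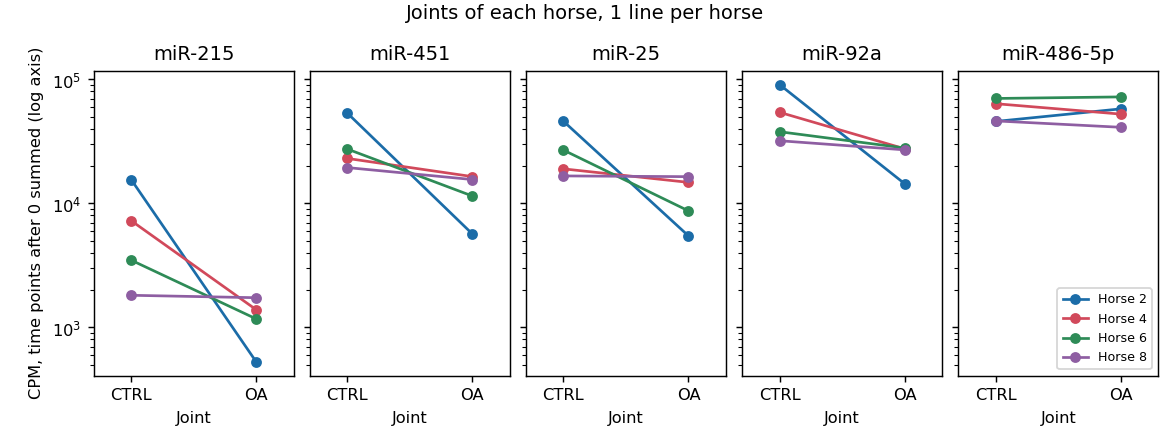
CPM of the counts after time point 0 summed per horse and joint (log axis, no TMM scaling), 1 line per horse, for 5 microRNAs. miR-215, miR-451, miR-25 and miR-92a fall from CTRL to OA in each of the 4 horses, most in horse 2 and least in horse 8 (miR-25 16679 to 16451 CPM), while miR-486-5p goes both ways.

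Among the lists, none had a member that passed over all features in this comparison. Adjusted over the list alone, 3 of 7 erythrocyte microRNAs (miR-451, miR-25, miR-92a), 3 of 7 of the miR-17~92 list (miR-25, miR-92a, miR-19b) and 1 of 3 liver microRNAs (miR-215) were lower in the OA joint, and 0 in each of the other 13 lists. As sets, the miR-17~92 list (adjusted p = 0.0117) and the erythrocyte list (0.0261) stood lower and the let-7 list (0.0261) higher in the OA joint with camera. Each had an adjusted p = 0.461 with an estimated correlation and 0.368 by fry. With the block the miR-17~92 list kept its call (0.0415), the erythrocyte and let-7 lists did not (0.0759 each), and without the pair of horse 2 at time point 49 no list passed. The inflammation-induced, chondrocyte, platelet and mesenchymal lists did not pass, with miR-21, miR-140-3p and miR-199a-3p uncalled.

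At single time points the joints differed in 1 feature. At time point 35 miR-126-5p, an endothelial microRNA, had 460 reads in the OA joint and 1 in the CTRL joint (edgeR adjusted p = 0.0229, n = 4 each). The ratio of the pooled reads was 632 (95% interval 113 to 24998, for counting error and not the spread between horses). miR-126-5p was higher in the OA joint of 3 of 4 horses, with 392 of the reads in horse 8 and 1 in horse 6. Its other arm, miR-126-3p, stood at 0.96 (SE 1.25) on the log2 scale. The call was lost when any horse was left out (adjusted p = 0.0828, 0.155, 0.197 and 0.545 without horses 2, 4, 6 and 8) and when only these groups were fitted, and over all settings the adjusted p ran from 1.74e-05 to 0.545.

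At the other time points edgeR called 0 of 139 features. Features at an unadjusted p under 0.05 numbered 23, 8, 21, 24, 13 and 3 at time points 0, 10, 42, 49, 56 and 63, and DESeq2 called 24, 21, 24, 20, 24 and 8. The leading features were mostly present in one joint and at 0 reads in the other. At time point 0 miR-8993 and miR-19a had 0 reads in the OA joint (at least 409.96-fold and 115-fold lower, adjusted p = 0.283 each), with reads in 2 and 3 of 4 CTRL libraries, while miR-182 had 149 reads against 0 (at least 32.2-fold higher). At time point 10 let-7g had 242 reads in the OA joint and 0 in the CTRL joint (at least 89.9-fold higher, 3 of 3 horses, adjusted p = 0.371), and miR-505 had 0 against 377, in 1 library (at least 108-fold lower). At time point 42 miR-151-5p had 764 against 0 reads (at least 162-fold higher, 4 of 4 horses) and miR-128 0 against 802 (at least 392-fold lower, 3 of 4 horses, adjusted p = 0.301 each). At time point 49 miR-100 had 0 against 738 reads (at least 107-fold lower, adjusted p = 0.0986) and miR-34c 228 against 0, in 1 library (at least 144-fold higher). At time point 56 miR-16 was at 11305 ± 5001 against 1208 ± 1040 CPM (log2 fold 3.21, SE 0.92, adjusted p = 0.106), and miR-8993 had 0 reads against 375. 3 of the 4 CTRL libraries and 0 of the OA libraries were in lane 1 there, and with lane as a covariate miR-16 stood at 2.30 (adjusted p = 0.547; range over settings 0.000145 to 0.69). At time point 63 miR-151-5p had 190 against 0 reads (at least 27.2-fold higher, adjusted p = 0.712) and miR-486-3p 0 against 28, in 1 library (at least 20.6-fold lower). Of the lists, the erythrocyte list at time point 63 was the one that passed camera (lower in the OA joint, camera adjusted p = 0.0401; adjusted p = 0.229 with an estimated correlation). By fry the endothelial list at time point 49 was the one that passed (lower in the OA joint, adjusted p = 0.0212), with 0 of 4 members called.

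Over time, no feature of the OA joint passed: 0 of 139 in edgeR, with 45 at an unadjusted p under 0.05, and 0 in DESeq2. The CTRL joint also gave 0 of 139 in edgeR, with 46 at an unadjusted p under 0.05, and 2 in DESeq2. Unchanged features of the simulated joints reached an unadjusted p under 0.05 in 21.7% and 20.6% of cases. With horse as a block the CTRL joint had 9 calls: miR-16 (adjusted p = 0.0297), miR-126-5p (0.033), miR-8993 (0.00723), miR-150 (0.0128), let-7c (0.0339), miR-192, miR-1, miR-25 and miR-342-3p. With block and lane 4 of the 9 passed, miR-126-5p, miR-8993 and miR-150 (0.0199 each) and miR-192 (0.0481), while miR-16 (0.12), let-7c (0.0643), miR-342-3p (0.0851), miR-25 (0.164) and miR-1 (0.181) did not, and with lane alone 0 passed. Without the block, the CTRL joint went from 0 to 3 calls without horse 2 and from 0 to 2 without its library of time point 49. Of the single contrasts, 2 passed in the CTRL joint. miR-16 fell at time point 56 (log2 fold -4.06, SE 0.96, adjusted p = 0.00733), to 1208 ± 1040 from 20425 ± 11711 CPM at time point 0 (with TMM scaling). Lane moved with this contrast, with 3 of 4 CTRL libraries in lane 1 at time point 56 and 1 of 4 at 0. With lane as a covariate the log2 fold was -3.48 (SE 0.95, adjusted p = 0.0466), and with block and lane -3.52 (SE 1.10, adjusted p = 0.136), no longer past the threshold. Horse 8, in lane 2 at both, went from 30468.5 to 1326 CPM (without TMM scaling), and horse 6, in lane 1 at both, from 457 reads to 1. The call was lost without horse 4, 6 or 8 (adjusted p = 0.132, 0.0942 and 0.166; lowest over these settings 0.00493). miR-126-5p fell at time point 35, to 1 read from 708 (ratio of time point 0 to 35 of 1482, 95% interval 265 to 58625, adjusted p = 0.0166). Its adjusted p = 0.0406 with lane as a covariate, and the call was lost with block and lane (0.099) and without horse 2, 4 or 6 (0.0635, 0.0789 and 0.435; lowest over these settings 0.0148). No single contrast passed in the OA joint in edgeR, with 12 to 24 features at an unadjusted p under 0.05 per contrast.

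The change over time differed between joints for miR-8993, 1 of 139 features in edgeR (adjusted p = 0.00214; range over settings 8.29e-08 to 1). Its reads alternated between the joints, each time in 1 or 2 libraries. At time points 0, 49 and 56 it had 823, 234 and 375 reads in the CTRL joint and 0 in the OA joint. At 10, 35 and 42 it had 0 in the CTRL joint and 261, 84 and 187 in the OA joint, and at 63 it had 25 and 169. Without horse 4 or horse 6 the call was lost (adjusted p = 0.0638 and 0.511), without horse 8 there were 3 calls, and DESeq2 called 1 feature, which was not miR-8993. With horse as a block miR-342-3p also passed (adjusted p = 0.0405).

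In plasma 10 of 92 features changed over time in edgeR: miR-8993 (adjusted p = 0.00639), miR-130a (0.0341), miR-144, miR-543 and miR-150 (0.0454 each), and miR-381, miR-214, miR-182, miR-1388 and miR-1468 (0.046 each). miR-130a was at 1368 ± 2319 CPM at time point 0, at 0 reads in all libraries at 42 and 49, and at 13956 ± 16019 CPM at 56 (n = 4 each). The red blood cell microRNA miR-144 had reads in 2 of 3 libraries at time point 10 (3734 ± 4113 CPM) and in 0 of 4 at 35, 42 and 49. All 10 were at 0 reads in every library of at least 2 and at most 4 of the 7 time points. No single contrast against time point 0 passed in edgeR, with 2 to 13 features at an unadjusted p under 0.05 per contrast. With horse as a block 0 passed in edgeR (12 at an unadjusted p under 0.05) and DESeq2 called 0. Leaving out horses 2, 4, 6 and 8 gave 3, 3, 7 and 1 calls, and without the 10 shallowest libraries 1 passed.

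MicroRNA as a percent of the library total did not differ past the threshold between fluids or joints. Plasma stood at 1.96% ± 1.52 and the CTRL joint at 0.627% ± 0.237 (SD, n = 4 horse sums each, two-sided exact permutation p = 0.143 over 70 arrangements, which allow p down to 0.0286). Without the 3 libraries rich in microRNA plasma stood at 0.427% ± 0.213 (exact permutation p = 0.257). The OA joint after time point 0 stood at 0.560% ± 0.159 and the CTRL joint at 0.690% ± 0.283 (SD, n = 4, exact permutation p = 0.486). As a percent of the reads of the spike-in UniSp2 (median of the libraries of a horse), microRNA stood at 1.26% ± 1.00 in plasma and 1.56% ± 0.523 in the CTRL joint (SD, n = 4, exact permutation p = 0.6, 0.6 adjusted over 3 comparisons). Without the 3 libraries plasma stood at 0.921% ± 0.504, lower than the CTRL joint in 4 of 4 horses (exact permutation p = 0.114, adjusted 0.343). After time point 0 it stood at 1.41% ± 0.394 in the OA joint against 1.77% ± 0.619 (exact permutation p = 0.343, adjusted 0.514). When and in what amount the spike-in was added is not given in the sources used here, so the ratio is not read as microRNA per volume of fluid.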

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

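Of the tests in this part, those of a common source, of red blood cell RNA and of a single library of horse 2 were chosen after the result was seen, as were the comparisons without the 3 plasma libraries and without that pair, also among the pairs in lane 2.

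Values far from the others of their group were found in 21 of 131 sets of values (16.0%) by Dixon's ratio, the gap to the nearest value over the range. Its critical values give about 1 in 20 for independent normal values. CPM and percents need not be normal, and sets that share a horse are not independent, so no excess over chance is read from this share. As a percent of the library total, microRNA stood apart in the plasma of horse 2 at time points 0 (5.86%) and 35 (1.37%) and in the CTRL joint of horse 2 at 49 (1.91%) and horse 8 at 56 (1.19%). Horse 4, the horse without a plasma library rich in microRNA, stood apart in the plasma sums in CPM of miR-125b-5p (4688), miR-146b-5p (1500.2), miR-148a (6814), miR-92a (46320), let-7a (9564), miR-192 (9680.0), miR-122 (723), miR-142-5p (4536) and miR-223 (1723), and horse 2 in miR-27a (2690.1). In the CTRL joint miR-221 stood apart in horse 6 (36149), miR-376c (741) and miR-382 (1449.7) in horse 4 and miR-451 in horse 2 (52077). After time point 0, miR-92a (14435) and miR-19b (3093) stood apart in the OA joint of horse 2 and miR-1180 (3.39) in the CTRL joint of horse 8. The change of miR-8993 over time differed between the joints by the interaction test (adjusted p = 0.00214).

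Plasma of 3 horses held libraries in which microRNA was over 5% of the total, led by miR-21 (23.4% to 25.1% of microRNA reads, median 4.86% and highest 23.0% in the other 23) and poor in miR-486-5p (0.0582% to 4.47% against a median of 39.8%). Thinned to 13070 reads, they still gave a median of 19 calls of plasma against CTRL joint over 20 thinnings, past the bound set beforehand (27 divided by 1.5), but their range of 15 to 23 spans it, so an effect of depth was afterwards left open. At a depth of 3916 reads the lowest correlation among the 3 was 0.877, above the median of 0.579 and the highest of 0.815 among the others and the highest of 0.8287 between the 3 and the others, which is consistent with RNA of a common source or with more captured molecules. Of the platelet list 7 of 7 members were higher in all 3, as set beforehand for platelet RNA, but miR-223, abundant in platelets, stayed at 45.0 to 396 CPM, so this was afterwards left open too. Beyond these sources of RNA no biological explanation was tested, since the 3 libraries come from different horses and time points.

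Lower miR-215, miR-451, miR-25 and miR-92a in the OA joint may reflect red blood cell RNA in the CTRL joint. miR-486-5p, abundant in red cells, had a log2 fold of 0.0174 (SE 0.26), above the bound of -0.5 set after the result was seen. It is 1 member, and the 7 erythrocyte microRNAs, with miR-451, miR-25 and miR-92a among them, had a median of -1.22. In the CTRL library of horse 2 at time point 49 miR-451 ranked 1 among CTRL libraries and miR-486-5p 18. A single member that need not follow miR-451 cannot decide this, so red blood cell RNA stays open. A difference between lanes as the whole cause is argued against by pairs with both joints in lane 2, with a median log2 fold of the 4 of -1.67 (median of their SEs 0.52). Without the pair of horse 2 at time point 49 it was -1.24 (0.52), beyond the bound of 0.5 times the fold with all pairs by barely more than that SE, and of the 4 taken singly this held for miR-25 alone. That pair carried part of the pattern among all libraries too: the median went from -1.38 to -0.84 (median of their SEs 0.26) without it, and in limma on mean log2 CPM per horse miR-25 turned (0.29). The median without the pair lies beyond the bound set for it, 0.5 times the fold with all pairs, by less than that SE, so the weight of this library stays open, as does the disease, which these tests do not address.

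miR-126-5p was nearly absent from the CTRL joint at time point 35. The 4 CTRL libraries held more microRNA reads than the 4 OA libraries (187280.0 against 136409), which argues against lower depth before any test. At the mean CPM of the OA joint they would hold 827 reads, and 174 without the OA library of horse 8, against 1 observed. If few molecules of this arm alone were the cause, the log2 fold of miR-126-3p would lie under 2 by more than its SE, and its 0.96 (SE 1.25) leaves that open. A biological difference between the joints stays open too.

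Chance could be tested by regrouping the same samples. For plasma against CTRL joint 1 of 35 splits, the real one, gave 27 calls, and the highest other gave 0. That share is under 0.05, but these splits ignore that both fluids came from the same horses. Of the 8 splits that part every horse, the real one alone gave as many and the highest other gave 0. As 8 are too few for a share under 0.05, chance stays open where the pairing is kept. Chance cannot be excluded for time point 35 (1 call, 13 of 35, highest other 2), for the difference between joints (1 call, 38 of 100, highest other 2) or for plasma over time (10 calls, 26 of 100, highest other 24). Where the real grouping gave 0 calls, every split gives as many whatever the data, so the splits say nothing about chance. This holds for the joints after time point 0 (35 of 35 splits, highest other 1), at time points 0 and 42 (35 of 35, highest other 0) and at 49 and 56 (35 of 35, highest other 1). It also holds for the OA joint over time (100 of 100, highest other 5) and the CTRL joint over time (100 of 100, highest other 9). Regrouping within horses gave as many in 18 of 40 for the difference between joints (highest other 2) and 9 of 40 for plasma over time (highest other 25). That some orders of the plasma libraries called more than the real one may come from a structure of the samples or from the liberal test over time, which were not told apart. At time points 10 and 63 the 10 splits are too few for a share under 0.05 (0 calls, 10 of 10, highest other 0).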

How the results depend on the processing

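Chosen after seeing the data were the settings without the 3 plasma libraries rich in microRNA, without the 10 libraries of 3916 to 8902 microRNA reads, and without the pair (also in lane 2 alone) or the CTRL library of horse 2 at time point 49. All other settings were set beforehand and all were run. Plasma against CTRL joint gave 23 to 33 calls with RLE, library size alone, no filter, a count minimum of 50, DESeq2, the block, the OA joint in place of CTRL and limma. DESeq2 gave 18 higher and 11 lower, a count minimum of 50 gave 15 and 8, limma on means 9 and 18. It fell to 0 at time point 0 alone (58 features tested), to 1 in lane 1 alone and to 2 without the 3 libraries. The OA joint against the CTRL joint after time point 0 went from 0 to 5 without a filter, 4 in DESeq2 and 2 without the pair of horse 2 with the block. At single time points DESeq2 gave 24, 21, 27, 24, 20, 24 and 8 calls in order of time. Time point 35 lost its call when fitted alone (0), and time point 56 gained 1 with library size alone. Over time the OA joint went from 0 to 46 without a filter. The CTRL joint went from 0 to 1 with library size alone and with no filter, 2 in DESeq2, 4 with block and lane and 2 without the CTRL library of horse 2. The difference between joints rose from 1 to 3 with block and lane. Plasma over time went from 10 to 1 with RLE, 35 without a filter, 0 with a count minimum of 50, 0 in DESeq2 and 1 without the shallow libraries. List calls went from 1 to 0 in plasma against CTRL joint with an estimated correlation and without the 3 libraries, from 3 to 0 in the joints after time point 0 with an estimated correlation and without the pair, and from 1 to 0 at time point 63 with an estimated correlation. Plasma minus CTRL joint in microRNA percent reversed to -0.200 without the 3 libraries. Fewer samples or features accompany the settings of time point 0, lane 1 and a count minimum of 50, and more features the setting without a filter. Otherwise the cause was not tested.

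With horse as a replicate block, the paired samples gave 3 calls in the joints after time point 0 (from 0), 9 in the CTRL joint over time (from 0), 2 in the difference between joints (from 1), 0 in plasma over time (from 10) and 1 list in the joints (from 3). It gave 28 calls in plasma against CTRL joint and changed no other count by over 1.5 times.

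Leaving out each horse in turn, calls ran from 8 (without horse 8) to 38 (without horse 4) in plasma against CTRL joint, with 9 without horse 6 and 19 without horse 2. They ran from 0 to 3 in the CTRL joint over time (3 without horse 2), from 0 to 3 in the difference between joints (3 without horse 8) and from 1 to 7 in plasma over time, and were 0 throughout in the OA joint over time and in the joints at each time point and together. The microRNA percent differed by 0.658 to 1.84 in plasma minus CTRL joint and by -0.199 to -0.0701 in OA minus CTRL joint.

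Of the values of named microRNAs, 1042 kept direction and side of the threshold under the planned settings, 202 lost and 74 gained a call, and 30 changed sign; under the added settings these were 140, 40, 5 and 4. No value passed after a change of sign. In plasma against CTRL joint these were, at time point 0 alone, miR-125b-5p (-0.053), miR-423-5p (0.74), miR-92a (1.48), miR-451 (1.83) and let-7a (0.088). In lane 1 alone they were miR-16 (0.90), miR-25 (0.50), miR-140-3p (0.44) and miR-342-3p (0.90). Against the OA joint they were miR-92a (0.26) and miR-451 (0.097), in limma miR-99a (-0.23), miR-92a (0.11) and miR-22 (-0.36), without the 3 libraries miR-92a (0.031), and without horse 4 miR-142-5p (-0.014, up to 1.07 without other horses). Between the joints miR-486-5p went from 0.017 to -0.025 with RLE, -0.014 with library size alone, -0.012 with no filter, -0.0067 in DESeq2, -0.022 with the block, -0.17 in limma and -0.022 without the pair with the block, and ran from -0.18 to 0.096 with a horse left out. miR-140-3p reversed to 0.37 with the block, 0.091 without horse 2 (lowest -0.85 without horse 6), 0.96 in limma, 0.54 without the pair and 2.44 without the pair with the block. miR-21 reversed to 0.037 without horse 2 (lowest -0.23 without horse 6), and in limma miR-25 (0.29), miR-16 (0.39) and miR-19b (0.046) did. The cause was not tested. Without the 10 shallowest libraries 123 features were tested (from 126) and 29 passed (from 27) in plasma against CTRL joint, and 113 were tested (from 92) and 1 passed (from 10) in plasma over time.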

Other observations

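Vesicles of both joints carried microRNAs linked to several cell types. Of 7 lymphocyte microRNAs (median log2 fold of plasma against CTRL joint -0.60, 1 called), miR-342-3p stood at 5204 ± 4802 CPM in the CTRL-joint sums against 789 ± 945 CPM in plasma (SD, n = 4, log2 fold -2.72, SE 1.11, edgeR adjusted p = 0.107), lower in plasma in 3 of 4 horses. Of its 7544 reads in the CTRL joint, 4825 were in the library of horse 2 at time point 49, without which the fold was -1.75 (SE 1.14, adjusted p = 0.341; range over settings 0.0107 to 0.817), and in lane 1 alone its direction turned (0.90). The more abundant miR-181a of the same list was higher in plasma in 4 of 4 horses (0.52, SE 0.31, adjusted p = 0.289). The myeloid microRNA miR-223 stood at 2287 ± 1172 against 499 ± 784 CPM (-2.20, SE 1.27, adjusted p = 0.281), also in 3 of 4 horses. The DLK1-DIO3 member miR-376c went the other way, at 188 ± 327 CPM in the CTRL joint and 2470.0 ± 1729 CPM in plasma (3.72, SE 1.94, adjusted p = 0.23). The OA joint against the CTRL joint gave let-7g at 2720 ± 935 against 1092 ± 307 CPM (1.32, SE 0.70, adjusted p = 0.682), higher in 4 of 4 horses. None of these 5 passed in edgeR with all libraries and the filter set beforehand.

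In the shallowest library, plasma of horse 2 at time point 42 with 3916 microRNA reads, miR-184 reached 335802 CPM, against a median of 0 CPM over the 26 plasma libraries. The CTRL-joint library of horse 2 at time point 49 was led by miR-92a, at 15.3% of the microRNA reads against a median of 3.64% in the other CTRL libraries, and miR-215 took 2.63% against 0.00295%, while miR-486-5p ranked 18 among 26 libraries at 4.32%.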
